A study of Drosophila melanogaster with 3 samples.

How the data were processed

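The data came from chromatin immunoprecipitation followed by sequencing (ChIP-seq) in Drosophila melanogaster. A transgenic line carried Achaete (Ac), a proneural basic helix-loop-helix transcription factor, fused to green fluorescent protein at its C terminus, and the tag was pulled down with an antibody against it. The material was whole embryos of both sexes collected 0 to 8 hours after laying. Chromatin was sheared by sonication, with a fragment size range of 200 to 800 bp per the labels. There were 3 biological replicates of this 1 group, numbered as the labels number them, and no second condition. The labels do not say whether the replicates came from separate collections, so the spread between them may be partly technical.

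For each replicate, the authors deposited a list of 30000 regions made from that replicate's alignments and a control alignment, before any reproducibility threshold, per the file headers and accompanying notes. A list of 30000 regions from the alignments of all 3 replicates together (the pooled list) and an optimal list were also deposited. Per those notes, the optimal list was derived from the replicate lists and the pooled list through the irreproducible discovery rate, a method that compares the ranks of regions between replicates. The peak caller, its version and the threshold of that method are not given in the sources used here. Lists existed on the dm6 and dm3 genome builds. The values used from each deposited region were its position, the offset of its summit, a signal value and the −log10 of a q value. The signal value is the authors' own, on a scale the deposited files do not state, and it served only to rank regions within 1 list, with ties broken by position. The −log10 q value in the deposited dm6 lists was used to count regions at q values of at most 0.05 and 0.01. The pooled list on dm3 was not used here. The peak lists hold no read counts, so the sequencing depth of each replicate is unknown. The control alignment itself was not analysed here.

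The dm6 lists were the main lists. Every dm6 region lay within the chromosome lengths of the release 6 assembly used as reference, and all regions were on the main arms 2L, 2R, 3L, 3R, 4 and X. Gene models were the 13944 protein-coding genes of FlyBase annotation release 6.54 on those arms and Y. No dm3 genome was used, so dm3 lists entered only counts and overlaps. Coordinates count from 1. Each replicate was represented by as many of its highest-ranked regions as the optimal list holds, 2756, called its top regions below. A region was counted as shared between replicates, and an optimal peak as present in a replicate's top regions, when the summits lay within 150 bp. A version of the optimal list without 1 replicate consisted of the optimal peaks present in the top regions of both other replicates, since the authors' thresholding could not be rerun from the lists. The positions, summits and signal values in such a version still came from all 3 replicates, so it is a subset with stricter support.

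Summits within 500 bp of an annotated transcription start of any gene were called promoter summits. The others were assigned in order to coding exon, 5′ UTR, 3′ UTR, intron or intergenic sequence. Chance values came from 100 random placements of the summits on the same chromosome, outside stretches of N. The smallest permutation p that 100 placements can give is 0.0099. A gene counted as bound when a summit lay inside it or within 2000 bp of either end. There were 25 gene lists, which were compared with all other protein-coding genes by an exact test stratified over 10 deciles of gene length. The test was two-sided, with Benjamini-Hochberg adjustment over the lists. Of the listed symbols, 7 were matched through a current symbol and 3 had no match. Neighbouring genes can share a summit and the lists share some members, so genes within a list are not independent. Motif matches on either strand were sought within 100 bp of the summit and in 2 windows of the same width centred 1000 bp to each side. The share at the centre was divided by the mean share in the flanks. An exact McNemar test, two-sided, compared the centre with 1 flank picked at random per peak, with adjustment over the 19 motifs. Fisher's exact test, two-sided, compared the 689 strongest with the 689 weakest peaks of the optimal list. The density ratio of X to the large autosomes carries an exact binomial 95% interval. Intervals cover counting error only.

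The genes named were fixed by rule before the data were examined. They were ac; every member of the list of proneural bHLH genes and partners; up to 4 members of each other called list and up to 2 of each list not called, by the rank of their strongest assigned peak; and the gene with the transcription start nearest to each of the 20 strongest peaks. Other members are named where a list's count is described, and neighbours where a summit lay at their start, after their values were seen. The lists, motifs, tests and 43 alternatives were also fixed before the data were examined. The alternatives covered other window widths, distances, top-list lengths, gene definitions, flanks, the dm3 lists and leaving out each replicate.

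The procedures were tested on simulated data. Among simulated lists of 15 long genes with no effect, 2.75% had an unadjusted exact-test p under 0.05 with length strata and 20.5% without, over 13944 genes. Lists of 15 genes of any length, bound at 40%, 60% and 80%, had such a p in 36%, 89.5% and 100% of draws with length strata. Simulated genes were drawn independently, unlike neighbours that share summits, and the last lists were not drawn toward long genes. The shares may therefore not hold for real lists of neighbouring or long genes. The real lists were called at adjusted p, so these shares are upper limits for how often such lists would be called. For 2756 random places, the motif ratio was 0.99 with no planted site and 2.22 with a site planted in 10% of them. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.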

Results

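Binding of GFP-tagged Ac in 0 to 8 hour Drosophila embryos was profiled in 3 biological replicates. The study names 1 group, so the comparisons below set the bound sites against random positions, length-matched genes and flanking sequence, and the replicates against each other. The authors' optimal list on dm6 held 2756 peaks, with a median width of 390 bp. Together they covered 858 kb, or 0.624% of the chromosome arms. All had a q value at or below 0.000968. These peaks were exactly the 2756 strongest regions of the pooled list by the authors' signal value. Being in the list therefore does not show that a given peak was ranked alike in the replicates. The dm3 version held 2454 peaks. The replicate lists all held 30000 regions, but the number at q of at most 0.05 was 3453 in replicate 1, 9954 in replicate 2 and 7898 in replicate 3. Since the depth of each replicate is unknown, these numbers were not compared by a test.

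The strongest regions recurred between replicates far more often than random positions did. Among the 2756 top regions of each replicate, 59.8% ± 5.16 (SD over 3 pairs) had a summit within 150 bp of a top summit of another replicate. Random placements gave a mean of 0.627% and a highest value of 0.871% (one-sided permutation p = 0.0099). Replicates 2 and 3 shared 63.8%, replicates 1 and 2 shared 61.5%, and replicates 1 and 3 shared 54.0%. In the 1000 highest regions, the mean share was 67.0% ± 6.86 (SD, 3 pairs), and in the full lists it was 30.2% ± 5.74 (SD, 3 pairs). Random placements at these lengths gave 0.244% and 6.59% (means over 3 placements).

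**Figure D1:**
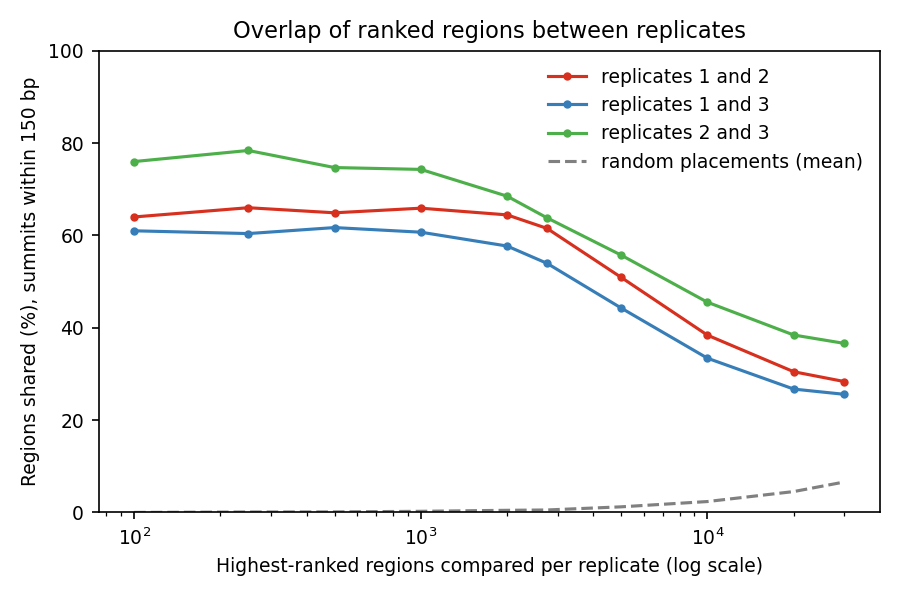
Percent of the highest-ranked regions of each replicate shared with another replicate (summits within 150 bp) against the number of regions compared (log scale), with 1 line per pair of replicates and a dashed line for random placements. At 2756 regions the pairs share between 54.0% and 63.8%, while random placements are below 1%. At 30000 regions random placements reach 6.59%.

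Of the 2756 optimal peaks, 1308 (47.5%) were present in the top regions of all 3 replicates, 893 in those of 2, 513 in those of 1 and 42 in none. Presence in a replicate's top regions averaged 75.3% ± 7.44 (SD, n = 3). Of the 689 strongest optimal peaks, 96.7% were present in the top regions of all 3 replicates. Of the 689 weakest, 1.89% were. The weakest peaks lie next to the rank where the top regions were cut, so their low share does not mean absence. In the full lists, 93.5%, 99.2% and 96.8% of all optimal peaks had a counterpart within 150 bp (replicates 1, 2 and 3). Across optimal peaks, the ranks in replicates 2 and 3 had a Spearman rho of 0.658, against 0.561 for replicates 1 and 2 and 0.497 for replicates 1 and 3. These correlations are across peaks, which are not independent replicates.

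The tagged gene itself, ac (FBgn0000022, X from 370031 to 370947, plus strand), had 2 assigned summits. Its strongest peak was at X from 369618 to 370155, with the summit at 369853, which lay 178 bp from the nearest annotated start. This promoter peak ranked 65 of the optimal list and 181 ± 192 in the replicates (mean, SD, n = 3), with 2 matches of the E-box bound by Achaete or Scute with Daughterless (GCAGSTG) within 100 bp. Across the achaete-scute complex, the group of related proneural genes that includes ac, 11 optimal summits were found between positions 350031 and 483176 of X, 6 of them with this E-box. All 11 also lay within CG32816, a gene annotated across the complex on the minus strand.

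Of the 11 genes in the list of proneural bHLH genes and partners, 4 were bound, against 1.62 among length-matched genes (exact test, adjusted p = 0.214), so the list was not called. Besides ac, these were sc, emc and hry. The proneural gene sc had 1 promoter summit at X 395969, 91 bp from its start, which ranked 2244 and had no counterpart in the full list of replicate 1. The gene emc, an inhibitor of proneural proteins, had 2 summits, the stronger at 3L 749431 (rank 961; 1841 ± 1128 in the replicates, SD, n = 3). The repressor hry (hairy) had 1 summit at 3L 8675813 (rank 1522; 2404 ± 1271 in the replicates, SD, n = 3). No summit was assigned to l(1)sc, ase, da, cato, ato, amos or tap. With genes extended by 5000 bp rather than 2000 bp, ase had 2 summits and sc had 5, and the counts of the other members were the same. The share of the list bound in the replicates' own top regions was 36.4% ± 9.09 (SD, n = 3).

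Genes of the Enhancer of split complex were all bound. Most encode Notch-responsive bHLH repressors or Bearded family proteins, while Kaz-m1 encodes a protease inhibitor and gro a co-repressor. All 13 members had a summit, against 1.58 among length-matched genes (exact 95% interval of the share 75.3 to 100%; exact test, adjusted p = 1.02e-11). The ratio, 8.23, lay between 4.80 and 18.4 over 8 alternatives, with 12.9 when replicate 2 was left out. All 13 were also bound in the top regions of every replicate. The members are neighbours on 3R and shared 18 distinct summits. The strongest, at 3R from 26039688 to 26040382 with the summit at 26040116, was 124 bp from the start of E(spl)m8-HLH (FBgn0000591) and ranked 11 (19.3 ± 24.8 in the replicates, SD, n = 3). It was also within 2000 bp of gro (FBgn0001139), at the end of the complex. Next came a promoter peak of E(spl)m4-BFM (FBgn0002629) with the summit at 3R 26024760, which ranked 33 (100 ± 131, SD, n = 3) and was also assigned to E(spl)m3-HLH. Each of these peaks held 1 match of the Ac/Sc-Da E-box.

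**Figure D2:**
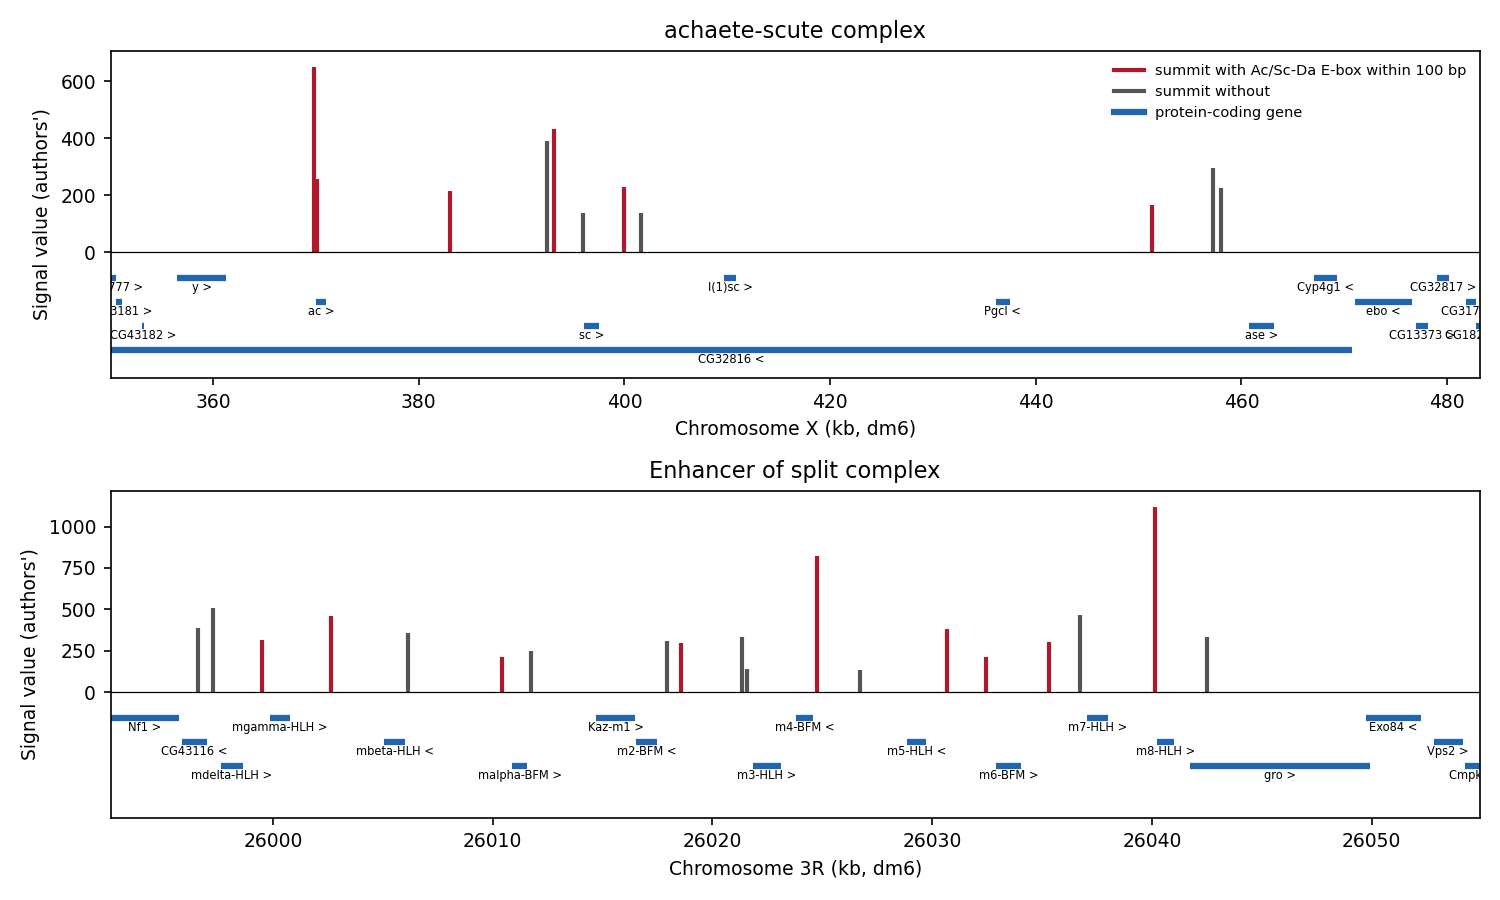
Optimal summits in the achaete-scute complex on X and the Enhancer of split complex on 3R, at their dm6 position (kb) and with height equal to the authors' signal value, with protein-coding genes below and > or < for their strand. Red bars hold an Ac/Sc-Da E-box within 100 bp of the summit and grey bars do not; 6 of 11 summits in the first region and 9 of 19 in the second are red.

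Genes active in sensory organ precursors, the cells that proneural proteins select to form bristles and other sense organs, were also bound more often. Of 18 members, 14 were bound against 5.84 among length-matched genes (77.8%, exact 95% interval 52.4 to 93.6%; exact test, adjusted p = 0.000981). In the replicates' own top regions the share was 83.3% ± 5.56 (SD, n = 3). The ratio, 2.40, lay between 2.23 and 4.10 over 8 alternatives. The strongest assigned peaks were those of insb, nvy, edl and chn. The insb (FBgn0034224) summit at 2R 17476271 was 1 bp from the start, ranked 90 (194 ± 190, SD, n = 3) and held 2 E-boxes. A promoter peak of nvy (FBgn0005636) had its summit at 2R 24275561, 173 bp from the start (rank 95; 256 ± 312, SD, n = 3). The gene edl, a regulator of ETS transcription factors (FBgn0023214), had 6 summits in and around it, the strongest in an intron at 2R 18672302 (rank 110; 236 ± 290, SD, n = 3). The zinc finger gene chn (FBgn0015371) had a promoter summit at 2R 15128714 (rank 112; 114 ± 8 in the replicates, SD, n = 3). No summit was assigned to scrt, ct, dpn or CadN.

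Of 15 Notch pathway genes, 10 were bound against 4.80 among length-matched genes (66.7%, exact 95% interval 38.4 to 88.2%; exact test, adjusted p = 0.0467). The replicates gave 68.9% ± 3.85 (SD, n = 3). The strongest peaks were at numb, an inhibitor of Notch (promoter, 2L 9449685, rank 98; 99.7 ± 41.0, SD, n = 3), and at neur, a ubiquitin ligase for Notch ligands (intron, 3R 9025025, rank 159; 249 ± 201, SD, n = 3), which is also on the list of sensory organ precursor genes. N itself had 3 summits, the strongest in an intron at X 3162502 (rank 467; 559 ± 211, SD, n = 3), and spdo had 1 promoter summit at 3R 30476517 (rank 533; 586 ± 438, SD, n = 3). Against 2.08 times the length-matched number here, the ratio lay between 1.69 and 3.52 over 8 alternatives (exact test, adjusted p from 0.000696 to 0.196). The call was lost with 5 of them. Of these, the 1000 strongest peaks (ratio 2.51, exact test, adjusted p = 0.196) and leaving out replicate 2 (ratio 2.26, exact test, adjusted p = 0.187) use fewer peaks. Starts within 1000 bp (ratio 2.59, exact test, adjusted p = 0.0792) and genes extended by 5000 bp (ratio 1.69, exact test, adjusted p = 0.15) lost it with all optimal peaks. Leaving out replicate 1 or 3 also uses fewer peaks and kept it (exact test, adjusted p = 0.0166 and 0.0182).

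Ribosomal protein genes were bound 5.01 times as often as length-matched genes. Of 92 members, 61 were bound against 12.2 (66.3%, exact 95% interval 55.7 to 75.8%; exact test, adjusted p = 5.61e-31), with 67.0% ± 5.99 in the replicates (SD, n = 3). The ratio depended on the gene definition, at 3.12 with genes extended by 5000 bp and 9.23 with only starts within 1000 bp. Of the 71 distinct summits assigned to them, 70 were promoter summits, 61 of them of a ribosomal protein gene and the others of neighbouring genes, and 2 held the Ac/Sc-Da E-box. Of the 61 bound genes, 60 had a summit within 500 bp of their own start. The strongest assigned summits were those of RpS27 (3R 25247504, 10 bp from the start, rank 43; 54 ± 34.1, SD, n = 3), RpL7 (2L 10201060, rank 105; 131 ± 90.6, SD, n = 3), RpS10b (X 19598012, rank 204; 215 ± 117, SD, n = 3) and RpL3 (3R 11226647, rank 224; 242 ± 42.7, SD, n = 3). The last lay 1474 bp past the 3′ end of RpL3 and 115 bp from the start of CG17726. Odorant and gustatory receptor genes were bound less often than length-matched genes, with 5 of 119 against 17.9 (4.20%, exact 95% interval 1.38 to 9.53%; exact test, adjusted p = 0.0017; 3.36% ± 1.46 in the replicates, SD, n = 3). The ratio of 0.28 was 0.0872 without replicate 1, 0.185 without replicate 2 and 0.0823 without replicate 3, and it lay between 0 and 0.467 over all 8 alternatives, each of which kept the call. The 4 of these with the strongest peaks were Or85f (rank 892), Gr89a (rank 1944), Gr39b (rank 2304) and Gr94a (rank 2312). The summits of Or85f and Gr94a lay past their 3′ ends, 72 bp from the start of RpL34b and 75 bp from that of p53.

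**Figure D3:**
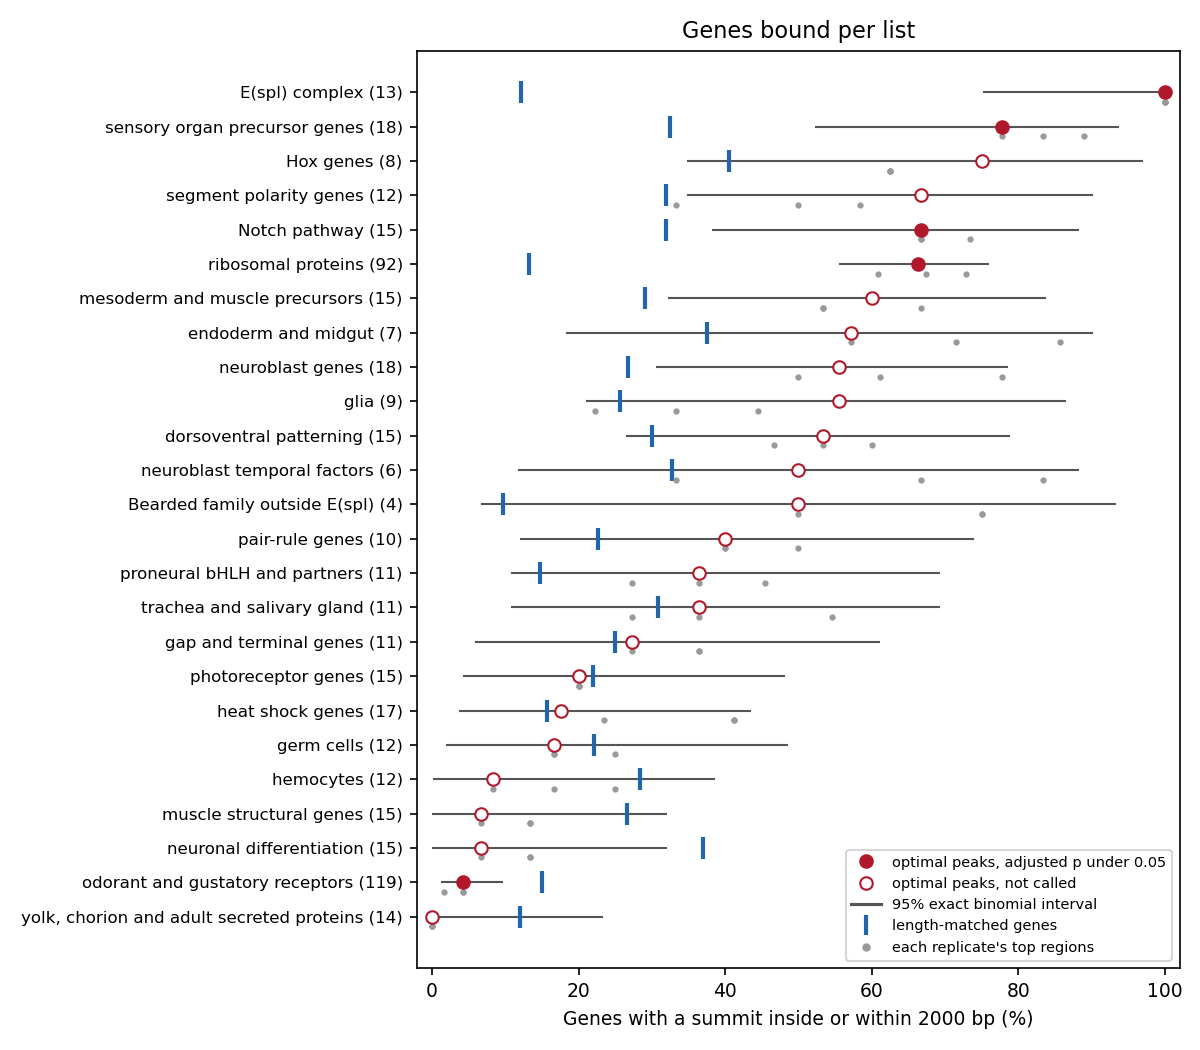
Percent of the genes in each of 25 lists (number of genes in brackets) with a summit inside the gene or within 2000 bp, with the exact binomial 95% interval as a line, the share in length-matched genes as a blue tick and each replicate's top regions as grey dots. Filled circles mark the 5 lists called at adjusted p under 0.05, of which the receptor list lies below its length-matched share.

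The other neural lists did not pass the test in the main setting. Among neuroblast genes, 10 of 18 were bound against 4.81 (ratio 2.08; exact test, adjusted p = 0.0564), with the strongest peaks at brat (intron, 2L 19155172, rank 66) and pros (3′ UTR, 3R 11392997, rank 190). This list was called with genes extended by 5000 bp (ratio 2.05; exact test, adjusted p = 0.0122) and without length strata (adjusted p = 0.00362), but not with the other 6 alternatives (adjusted p up to 0.758). Among the temporal factors of neuroblasts, 3 of 6 were bound against 1.97 (exact test, adjusted p = 0.765), led by grh (rank 132) and pdm2 (rank 1312). Only 1 of 15 neuronal differentiation genes was bound, against 5.54 (exact test, adjusted p = 0.0606). That gene was elav, with a promoter summit at X 523495 (rank 70; 80 ± 4.36, SD, n = 3). Among glial genes, 5 of 9 were bound against 2.31 (ratio 2.16; exact test, adjusted p = 0.201), led by loco (rank 1190) and moody (rank 1202). The share in the replicates' own top regions was lower, 33.3% ± 11.1 (SD, n = 3), and with a replicate left out the ratio was 1.31 to 1.90. In the Bearded family outside the E(spl) complex, 2 of 4 were bound, Brd and Tom (exact test, adjusted p = 0.201). Each had 2 summits, and the stronger, at rank 1601, was the same for both.

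None of the patterning and tissue lists was called either. Segment polarity genes had 8 of 12 members bound against 3.83 (ratio 2.09; exact test, adjusted p = 0.0702), led by fz (rank 78) and nkd (rank 93). The replicates' own top regions gave a lower share, 47.2% ± 12.7 (SD, n = 3), and with a replicate left out the ratio was 1.24 to 1.85. Of 15 mesoderm and muscle precursor genes, 9 were bound against 4.37 (exact test, adjusted p = 0.0606), led by Mef2 (2R 9959928, rank 64) and stumps (rank 392). The Mef2 summit lay 1070 bp before its own start and 150 bp from that of Pal1. Hox genes had 6 of 8 bound (exact test, adjusted p = 0.201), led by lab (rank 325) and Antp (rank 401, with 8 summits). Dorsoventral patterning genes had 8 of 15 bound (exact test, adjusted p = 0.201), led by ush (rank 8) and sim (rank 359). Pair-rule genes had 4 of 10 (slp1, rank 273; exact test, adjusted p = 0.462), gap and terminal genes 3 of 11 (oc, rank 296, and knrl, rank 1404; exact test, adjusted p = 1), endoderm and midgut genes 4 of 7 (lab, rank 325, and fkh, rank 462; exact test, adjusted p = 0.635), and trachea and salivary gland genes 4 of 11 (trh, rank 366; exact test, adjusted p = 1). Muscle structural genes had 1 of 15 bound (Act87E, rank 1463; exact test, adjusted p = 0.201), hemocyte genes 1 of 12 (ush; adjusted p = 0.298), germ cell genes 2 of 12 (CycB, rank 19, and ovo, rank 1459; adjusted p = 1), photoreceptor genes 3 of 15 (led by Rh5, rank 528, and norpA, rank 605; adjusted p = 1), heat shock genes 3 of 17 (led by Hsp83, rank 191, and Hsp23, rank 510 and shared with Hsp27; adjusted p = 1), and yolk, chorion and adult secreted protein genes 0 of 14 (adjusted p = 0.333). Over all 13944 genes, 2644 (19.0%) were bound.

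The strongest peak of the optimal list was a promoter peak of px (plexus), at 2R from 22514115 to 22514488 with the summit at 22514305, 206 bp from a start. It ranked 1 in all 3 replicates. The next 3 were a promoter peak of CG14100 (3L 19590621), a promoter peak of ph-p, a Polycomb group gene (X 2137340), and an intronic peak of sbb (2R 18337173). The genes with a start nearest to peaks 5 to 10 were hll, cno, CG1888, cbt, mRpS10 and Psc, another Polycomb group gene. E(spl)m8-HLH had peak 11. Peaks 12 to 20 were nearest to Chro, cpo, croc, CG11050, eEF1gamma, Ugalt, zfh2, CycB and RYBP. Peaks 5, 10, 14, 16, 18 and 20 lay more than 2000 bp from the gene named, so they were not assigned to it. Peak 8, nearest to the start of cbt, lay inside ush. The mean rank of these 20 peaks in the replicates lay between 1 and 36.7. Of the 20, only the peak at E(spl)m8-HLH held an Ac/Sc-Da E-box within 100 bp of the summit.

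Summits were concentrated at transcription starts and rare in coding exons. Of the optimal summits, 1024 (37.2%) lay within 500 bp of a start, against 11.5% of random placements (3.23 times; one-sided permutation p = 0.0099). The replicates' own top regions gave 37.0% ± 0.832 (SD, n = 3). A further 1031 summits (37.4%) were in introns and 634 (23.0%) were intergenic, against 39.2% and 30.3% of random placements. Coding exons held 16 summits (0.581%), against 14.1% of random placements (one-sided permutation p = 0.0099 for fewer).

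Sequence at the summits was enriched for the E-box of Ac with Daughterless. The motif GCAGSTG (S for C or G) occurred within 100 bp of 493 of 2756 summits (17.9%), against 7.38% of flanking windows, a ratio of 2.42 (exact McNemar test, adjusted p = 1.42e-31). The ratio in the replicates was 2.22 ± 0.464 (SD, n = 3), at 1.69 in replicate 1, 2.52 in replicate 2 and 2.46 in replicate 3. Among E-box cores, CAGCTG had a ratio of 2.11 (adjusted p = 2.73e-25; 2.00 ± 0.416 in the replicates, exact McNemar test, SD, n = 3) and CAGGTG had 1.76 (adjusted p = 3.77e-12; 1.66 ± 0.188, exact McNemar test, SD, n = 3). CATATG passed at 1.22 (exact McNemar test, adjusted p = 0.0492), but lost the call with 7 of 8 alternatives, leaving out any of the replicates included (ratios from 1.16 to 1.18 with a replicate left out; exact McNemar test, adjusted p from 0.0158 to 1 over the 8). The cores CACGTG, CAATTG, CATCTG, CAAGTG, CACATG, CAAATG and CAACTG, the last searched as CAGTTG, had ratios between 0.895 and 1.15 and did not pass.

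Motifs of other factors were enriched as well, and 9 of 19 motifs passed in all. The DNA replication-related element (DRE, TATCGATA), found at promoters of broadly expressed genes, had a ratio of 2.47 (1.52% against 0.617%; exact McNemar test, adjusted p = 0.00261) and the M1BP promoter motif 2.59 (0.798% against 0.308%; exact McNemar test, adjusted p = 0.0101). Among peaks over 500 bp from a start, these ratios were 0.353 and 0.40 and were not called. The DRE call was lost with 2 of 8 alternatives and the M1BP call with 6, among them leaving out replicate 1 (ratio 2.89) or 2 (ratio 2.67; exact McNemar test, adjusted p = 0.203 and 0.523, highest over the 8 alternatives 0.615). The motif of Zelda, the activator of the early zygotic genome, had a ratio of 1.71 (exact McNemar test, adjusted p = 0.00773). It lost its call with 4 of 8 alternatives, among them leaving out replicate 2 (ratio 1.55) or 3 (ratio 1.61; exact McNemar test, adjusted p = 0.235 and 0.368, the latter the highest of the 8). At the 2059 optimal peaks without the Ac/Sc-Da E-box within 200 bp, the Zelda ratio was 1.02 (exact McNemar test, adjusted p = 0.884). The GAGA factor motif had a ratio of 1.56 (exact McNemar test, adjusted p = 4.48e-05), but 0.99 among the 1000 strongest peaks. Its call was lost with 5 of 8 alternatives, among them leaving out replicate 2 (ratio 1.17) or 3 (ratio 1.21; exact McNemar test, adjusted p = 0.794 and 0.621, highest over the 8 alternatives 0.802). With windows of 200 bp its ratio was higher, 2.02 (exact McNemar test, adjusted p = 1.76e-19). GAGA factor matches were densest beside the summit, at 0.791 per kb in the bin centred at -175 bp, against 0.334 in the bin at -25 bp. The BEAF-32 core CGATA was found at 23.0% of summits against 20.9% of flanks (exact McNemar test, adjusted p = 0.029). This call was lost with 6 of 8 alternatives, among them leaving out replicate 2 (ratio 1.13) or 3 (ratio 1.11; exact McNemar test, adjusted p = 0.225 and 0.457, highest over the 8 alternatives 0.645). The motifs of Su(H), Opa/Zic and Twist/Snail did not pass, with ratios of 1.07, 0.909 and 1.25. The last passed with 1 of 8 alternatives, leaving out replicate 2 (ratio 1.45; exact McNemar test, adjusted p = 0.0269, against 0.123 to 1 with the others).

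**Figure D4:**
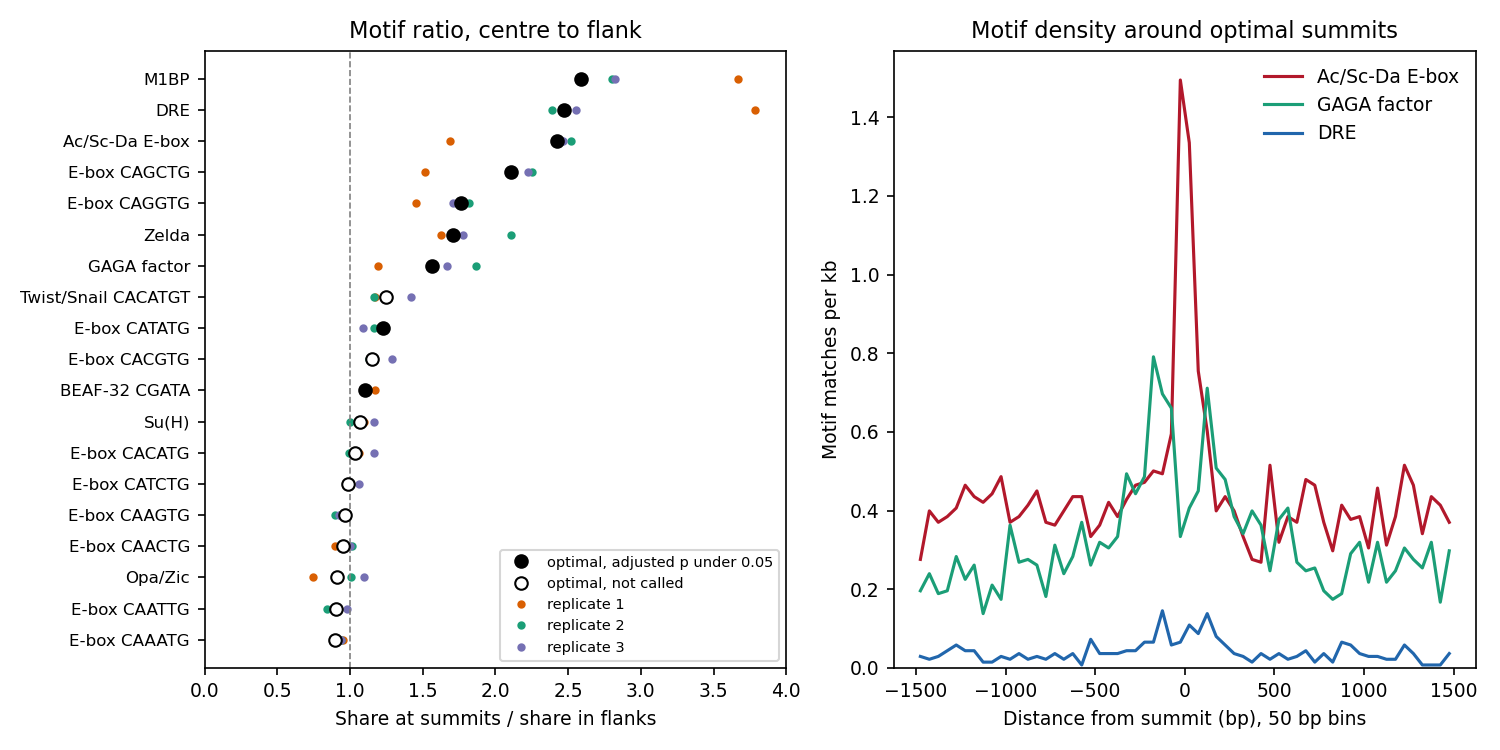
Left, ratio of the share of summits with a motif within 100 bp to the share in flanking windows, for 19 motifs in the optimal list (black, filled at adjusted p under 0.05) and in each replicate's top regions (coloured dots). Right, motif matches per kb in 50 bp bins around the optimal summits, where the Ac/Sc-Da E-box peaks at the summit and the GAGA factor and DRE motifs do not.

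No difference in E-box share was detected between strong and weak peaks. Of the 689 strongest optimal peaks, 132 held it (19.2%, exact 95% interval 16.3 to 22.3%), and of the 689 weakest, 113 did (16.4%, exact 95% interval 13.7 to 19.4%). The odds ratio was 1.21 (Fisher's exact test, two-sided, p = 0.205). The direction turned in the version without replicate 1 (odds ratio 0.767, Fisher's exact test, p = 0.133). That version still ranked peaks by the signal of all replicates and kept only those in the top regions of both others. This selection may itself change which peaks are weakest, so the turn does not show how strength and E-box relate without replicate 1.

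Chromosome X, which is present in fewer copies than the autosomes in a mixture of both sexes, held fewer peaks per megabase. Its 412 summits gave 17.5 per Mb against 21.4 per Mb on 2L, 2R, 3L and 3R, a ratio of 0.82 (exact binomial 95% interval 0.736 to 0.911). The replicates gave 0.771 ± 0.0801 (SD, n = 3), with all 3 below 1. Whether the copy number of X accounts for the lower density was not tested. Chromosome 4 held 17 summits, and none was on Y.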

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

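No paired analysis was possible because the series has 1 group. The overlap between replicates, the promoter share and the E-box ratio kept their direction and stayed past the threshold under every alternative tried, the replicates left out included. The E-box ratio ranged from 1.80 with windows of 200 bp to 5.45 against shuffled sequence. The number of optimal peaks was 1308 when only those in the top regions of all 3 replicates were counted, and from 1446 to 1703 with a replicate left out, which follows from the support these versions require. With no length strata, 9 lists rather than 4 were bound more often, with neuroblast, segment polarity, Hox, dorsoventral and mesoderm genes added. Simulated lists without an effect then had an unadjusted exact-test p under 0.05 in 20.5% of draws. Of the 4 called lists, E(spl) complex, sensory organ precursor genes and ribosomal proteins kept their call under all 8 alternatives. The number of summits assigned to a named gene depended on the gene definition: of 78 genes, 43 had another number with only starts within 1000 bp and 23 with genes extended by 5000 bp. The number of enriched motifs was 5 with windows of 50 bp, 3 in the 1000 strongest peaks, 4 for peaks over 500 bp from a start, and from 5 to 7 with a replicate left out. Fewer peaks entered the last 3 of these. The odds ratio of the E-box between the strongest and weakest peaks lay between 0.767 and 1.31 with a replicate left out. Peaks there were still ranked by the signal of all replicates, so this range does not show the effect of removing a replicate's signal. With a replicate left out, the X to autosome ratio lay between 0.768 and 0.907. Changes of direction otherwise concerned lists not called in either setting and motifs, and the cause was not tested. With the 1000 strongest peaks, the ratio to length-matched genes was 0 for Bearded family genes and for glia, 0.78 for gap genes, 0.966 for pair-rule genes and 1.38 for photoreceptor genes. The motif ratio there was 0.99 for GAGA factor and 0.85 for Su(H). With peaks in the top regions of all 3 replicates, the ratio to length-matched genes was 0 for Bearded family genes, 0.631 for gap, 0.772 for pair-rule, 0.998 for Hox, 1.37 for germ cell and 1.65 for photoreceptor genes. With genes extended by 5000 bp, it was 0.905 for heat shock, 1.08 for photoreceptor, 1.15 for hemocyte and 1.32 for germ cell genes. Hox genes were at 0.572 with starts within 1000 bp, and without strata heat shock genes were at 0.931 and photoreceptor genes at 1.05. With flanks at 500 bp, the motif ratio was 0.803 for Su(H), 0.868 for CACATG, 1.06 for Opa/Zic, 1.07 for CAACTG and 1.14 for CATCTG. With windows of 50 bp it was 0.849 for CACGTG, 0.973 for CACATG and 0.978 for Su(H), and with windows of 200 bp 1.01 for CATCTG, 1.05 for CAACTG and 1.07 for CAAGTG. Over 500 bp from a start it was 0.353 for DRE, 0.40 for M1BP, 0.932 for Su(H), 0.933 for CACGTG and 1.16 for CATCTG. Leaving out a replicate gave 0 to 7.50 for Bearded family, 0.824 to 2.07 for Hox, 0.527 to 1.03 for gap, 1.11 to 1.25 for germ cell, 0.711 to 1.93 for pair-rule and 1.34 to 1.51 for photoreceptor genes. For motifs it gave 0.963 to 1.03 for CACATG, 0.89 to 1.03 for CATCTG, 0.982 to 1.07 for Opa/Zic and 0.932 to 1.03 for Su(H). Read depth is unknown, so what it limits could not be assessed.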

Other observations

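The comparisons of E-boxes between gene lists and between promoters and other sites, the count of 6-base words, the bases beside the E-box core and the tests of other E-box forms and of summit precision were chosen only after the results above were seen. Summits assigned to the E(spl) complex and to sensory organ precursor genes held the Ac/Sc-Da E-box within 100 bp in 33 of 67 cases (49.3%). Those assigned to ribosomal protein genes held it in 2 of 71 (2.82%; odds ratio 33.5, Fisher's exact test, two-sided, p = 7.49e-11). This p treats summits as independent, although 18 of the 67 lie in the E(spl) complex. The groups also differed in place, with promoter summits making up 70 of 71, against 13 of 18 in the E(spl) complex and 14 of 49 for sensory organ precursor genes. Among all optimal summits, 17.9% held the E-box. It was present at 9 of 25 summits of neuroblast genes (36%) and 6 of 23 of Notch pathway genes (26.1%). None of the 16 summits of Hox genes and none of the 13 of mesoderm and muscle precursor genes held it. Promoter summits held it in 15.1% of cases and other summits in 19.5% (odds ratio 0.736, Fisher's exact test, p = 0.00395). The gene assigned the most summits was CG32816, which spans the achaete-scute complex, with 13, the same number as CG1677. Genes with 6 included phyl (5002 bp long) and edl (6010 bp long), both on the list of sensory organ precursor genes.

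Enrichment of the E-box core was also counted by the base before it, and differences between bases were not tested. GCAGCTG was 2.69 times and ACAGCTG 2.63 times as frequent at summits as in flanks, against 1.39 times for CCAGCTG and 1.87 times for TCAGCTG. CAGCTG reads the same on both strands, so some of these matches also had G before the core on the other strand. For the other core, ACAGGTG was at 2.55, GCAGGTG at 2.12, CCAGGTG at 1.42 and TCAGGTG at 1.14 (exact binomial test, adjusted p = 0.461 for the last). Of 2080 words of 6 bases counted once per window and strand pair, 268 were more and 440 less frequent at summits than in flanks (exact binomial test, adjusted p under the threshold of 0.05). CAGCTG had the highest ratio of those that passed, 2.11. It was followed by ACAGTG at 1.99, GTGCAC at 1.98 and ACACTG at 1.96, none of them among the 19 motifs.

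Replicate 1 had fewer E-boxes at its top summits than the others, 12.4% against 18.9% and 18.5%. Its 876 top regions unmatched in replicates 2 and 3 had a ratio of centre to flank of 0.915, against 2.47 for the unmatched regions of replicate 2 and 2.25 for those of replicate 3, so more background among them may account for part of the difference. Its 1880 matched regions also had a lower share, 15.1% (ratio 2.05), than those of replicate 2, 19.0% (2.54), and of replicate 3, 19.4% (2.55), a difference that was not tested and whose cause stays open. Less precise summits in replicate 1 stay open as a cause. At 1404 regions of replicate 1 that overlapped top regions of both others, the E-box share within 50 bp of its summits was compared. It was 0.923 times the mean of the others (bootstrap 95% interval 0.824 to 1.04). Overlap limits the distance between summits, so regions with far displaced summits drop out and this ratio cannot decide the question. A top summit of another replicate lay within 500 bp of 114 of the 876 unmatched regions of replicate 1. The counts were 89 of 614 (14.5%) in replicate 2 and 131 of 808 (16.2%) in replicate 3. Nearby summits were thus not more common at the unmatched regions of replicate 1. The test set beforehand, which gave 0.946, was void because it kept only summits within 150 bp of each other, and no biological explanation was tested.

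Most strong peaks lacked the Ac/Sc-Da E-box, which 19.2% of the 689 strongest held. Most weak peaks lacked it too, as 16.4% of the 689 weakest held it. The tests below used optimal peaks of any strength, so they do not describe strong peaks in particular. At the 2059 optimal peaks without it within 200 bp, CAGCTG with no G before it on either strand was 1.56 times as frequent at the centre as in the flanks (6.75% against 4.32%, exact McNemar test, p = 7.6e-05), so binding through other forms of the E-box may account for a small part. The test set beforehand, of the cores after any base, gave at most 0.918 but was void, because these peaks were picked for lacking GCAGSTG at the centre and not in the flanks. Pull-down of highly transcribed genes may account for another part, given the ratio of 5.01 for ribosomal protein genes (3.12 to 9.23 over 8 alternatives), but their 71 summits made up 2.58% of the optimal list. The length-matched genes were not matched for expression or accessibility. The ratio therefore cannot tell this explanation from open chromatin. For open chromatin shared with other factors, the GAGA factor motif had the lowest ratio of 3 motifs at peaks without the E-box, 1.39, against 2.56 for DRE and 2.13 for M1BP. Of these, only DRE passed (exact McNemar test, adjusted p = 0.00894, against 0.166 for M1BP and 0.137 for GAGA factor). The GAGA factor ratio met neither bound set beforehand, so this explanation stays open. Binding data of other factors or accessibility data would be needed to decide. Among the 1000 strongest peaks, with or without the E-box, the ratio was 0.99 for GAGA factor, 2.0 for DRE and 2.8 for M1BP, none of them called.

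Regions of the pooled list were dense around the tagged gene, with 22 within 10000 bp of ac, a density above that of 99.8% of the 2196 genes on X. Extra copies of ac in the transgenic line could raise it, and the value has the direction they require. The density per 10 kb, 10.5 for ac, was also high across the complex, at 13.5 around sc, 12.3 around l(1)sc and 8.02 around ase, which lie 25.1, 38.8 and 89.8 kb from ac, and on 3R it was 10.5 around E(spl)mgamma-HLH and 7.70 around E(spl)m8-HLH. Densities near or above that of ac thus occurred elsewhere too, but those in the complex do not exclude extra copies, since neither the length of the transgene nor the number of copies in the line is given in the sources used here. Many E-boxes in the regulatory DNA of the complex may also raise it, but the E-box share of these regions, 18.2%, was 1.80 times that of other X regions, with too few regions to decide (Fisher's exact test, p = 0.273).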
